A study of Mus musculus with 26 samples.

How the data were processed

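RNA was sequenced from mouse intestinal organoids, cultures of small epithelial structures grown in Matrigel from isolated crypts of C57BL/6 mice, in medium holding EGF, Noggin, R-spondin, CHIR-99021, which activates Wnt signalling, and Y-27632, per the labels' protocols. Organoids received vehicle, arachidonic acid (AA, 25 µM) or prostaglandin E2 (PGE2, 50 nM) and were collected on days 1, 3 or 6. The treatment protocol names PGE2, while the series' design text names a dimethyl PGE2 analogue. Which compound was used is not given in the sources used here, and "PGE2" below stands for either. RNA was taken up in Trizol and libraries were made with a directional NEBNext Ultra II kit, per the labels' protocols. There were 26 libraries in 8 groups: vehicle, AA and PGE2 at days 1 and 3 with 3 libraries each, and vehicle and AA at day 6 with 4 libraries each. Every library column was matched to its sample through the library names in the file headers, and 0 columns remained unmatched. The labels do not say whether replicates were separate cultures, separate mice or repeated libraries, so each p-value below measures only the spread between these libraries.

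The values are raw counts of reads per gene, whole numbers with different totals in each library, as the authors deposited them in 2 tables, 1 for days 1 and 3 and 1 for day 6. Cutadapt, STAR, DESeq2 and limma 3.46 are named without their roles, per the submitters' processing notes. The counting program, its strand setting and the annotation release are not given in the sources used here. The genome build is named as GRCh38.p6, a human build, per the submitters' processing notes, while the gene identifiers in the tables are mouse Ensembl identifiers, so no genome positions are printed. Each table lists the same 55385 identifiers, of which 55144 (99.6%) matched a gene name; the other 241 held 0.00250% of the counts. Total counts per library were 1.01e+07 to 1.46e+07 at days 1 and 3 and 1.61e+07 to 1.98e+07 at day 6. Expression is given as CPM, the usual count scaled to a fixed library total, and values under 1 CPM, which rest on few reads, carry a large counting error.

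The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups of the table, library sizes were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with robust spread and 1 mean per group was fitted to the 18 libraries of days 1 and 3 (14850 genes, 12 residual degrees of freedom) and separately to the 8 libraries of day 6 (14663 genes, 6 residual degrees of freedom). Contrasts were AA against vehicle at days 1, 3 and 6, PGE2 against vehicle at days 1 and 3, AA against PGE2 at days 1 and 3, vehicle at day 3 against day 1, and 3 differences of responses: the response to AA at day 3 minus day 1, the response to PGE2 at day 3 minus day 1, and the response to AA at day 6 minus day 3, the last in a joint fit of all 26 libraries. These 11 comparisons use p-values adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and a gene is said to have risen, fallen or changed only when it passed. Log2 fold changes are those of the fitted model and are given with a standard error taken from the quasi-likelihood F statistic; CPM values are means ± SD over the libraries of a group after TMM scaling, with no prior count.

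Genes were named by a rule fixed before the data were examined. For each treatment against vehicle it took up to 6 rises and up to 6 falls with the largest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 1, with every treated library beyond every vehicle library, leaving out predicted genes. For the other comparisons it took up to 4 in each direction, for differences of responses by size and threshold alone. It also took up to 4 members with the smallest p of each gene list that passed its test or held at least 3 called members, and a panel of 18 genes wherever they were measured. Genes outside this rule are marked as chosen after their values were seen.

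The 25 gene lists were also fixed before the data were examined: crypt base columnar stem cell, fetal-like and regenerative epithelium, YAP/TEAD target, Wnt target, proliferation, Paneth cell, goblet cell, enteroendocrine cell, tuft cell, enterocyte, cAMP/CREB early response, prostanoid and eicosanoid pathway, fatty acid oxidation and PPAR target, fatty acid synthesis and desaturation, cholesterol synthesis, NRF2 and oxidative stress, unfolded protein and integrated stress response, interferon response, antigen presentation, chromatin modifier, heat shock, mitochondrially encoded, fibroblast and smooth muscle marker, immune cell marker, and endothelial and neural marker. They were written from general knowledge of the cell types and pathways, and some genes stand in more than 1 list. Each list was tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between members, adjusted over the lists within a comparison. Because members of a list can vary together, camera was also run with the correlation estimated from the libraries, and fry, which asks whether the members of a list move on balance in 1 direction, was run as well. A list call that was lost with an estimated correlation has that adjusted p beside it. Calls of members were counted over all genes tested and, separately, adjusted over the list alone. In the comparisons of AA with PGE2, of vehicle between days and of responses between days, only part of the called lists is described in the text. Some named genes are not reported here, though they stay in the fits, lists and counts. A further 4 lists were written after the values were seen and are used only in the closing part.

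The overlap of the AA and PGE2 responses was measured by Pearson's r and Spearman's rho across genes, and by calls in the same direction against the number given by the product of the list sizes. Genes are not independent replicates, so these carry no p-value. Because both responses subtract the same vehicle libraries, the correlation and covariance were compared with 100 simulated draws in which neither treatment changed any gene. Splitting the 3 vehicle libraries into separate controls was not possible, as it would leave 1 side with a single library.

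The test was tried on counts simulated from the real means, spreads and library sizes, with 50 genes changed at each of 4 fold changes. For AA at day 1 (14705 genes), 50% of genes changed 1.25-fold were called, 82% at 1.5-fold, 94% at 2-fold and 100% at 4-fold. For AA at day 6 (14375 genes) the shares were 36%, 82%, 94% and 100%. Between 3.11% and 7.43% of simulated calls in the 5 treatment comparisons were false. Far more genes were called in the real data, so these shares need not hold there.

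The alternatives tried were scaling by RLE or by total counts, no filter on low counts or a filter of at least 1 CPM in at least 3 libraries (4 at day 6), limma-voom and DESeq2 1.42.0 in place of edgeR, a replicate block, a fit to only the groups in a contrast, a threshold of 0.01, a minimum of 1.5-fold, a minimum log2 CPM of 3 for the correlations, leaving out each library in turn and, chosen after seeing the data, removing the rRNA-like and mitochondrial genes. The closing part gives their effect. Spread between replicates was also compared with counting error by a chi-square over genes with at least 20 summed counts. Reads shared between close paralogs, among them the alpha-defensin (Defa) genes, cannot be assigned from gene counts alone.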

Results

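The data were gene counts from 26 RNA libraries of mouse intestinal organoids given vehicle, AA, a dietary polyunsaturated fatty acid that cells can convert to prostaglandins, or PGE2, the main prostaglandin made from it. Vehicle, AA and PGE2 were each measured at days 1 and 3 (n = 3 libraries per group), and vehicle and AA at day 6 (n = 4 per group). Total counts ran from 1.01e+07 to 1.46e+07 per library at days 1 and 3 and from 1.61e+07 to 1.98e+07 at day 6. Mitochondrial ribosomal RNA took 6.74% to 10.3% of the counts of each library at days 1 and 3 and 0.00305% to 0.266% at day 6, while the other mitochondrial genes took 1.45% to 2.13% and 3.16% to 5.23%. The rRNA-like loci Gm26917 and Gm42418 took 5.43% to 12.1% and 5.10% to 8.63%. Treatment day and this difference in library content could not be separated. The day 6 libraries were thus tested against earlier ones only as a difference of responses.

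At days 1 and 3 the first principal component (46.4% of the variance) placed the libraries in the order vehicle, AA, PGE2 on both days, and the second component (21.1%) separated day 1 from day 3. At day 6 the first component (51.0%) separated AA from vehicle, and vehicle replicate 4 lay apart from the other 3 vehicle libraries, at -37.9 on the first component and -24.2 on the second component (16.2%). Differences between replicates exceeded counting error in each of the 30 pairs of replicate libraries, with a chi-square per degree of freedom between 1.24 and 25.2.

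**Figure D1:**
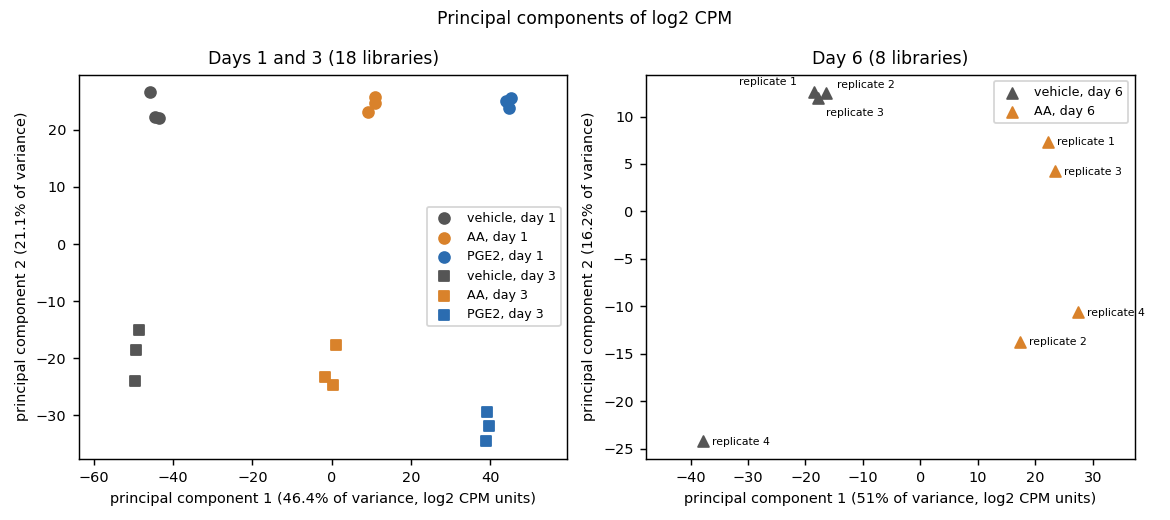
Principal components of log2 CPM for the 18 libraries of days 1 and 3 and, separately, for the 8 libraries of day 6; each point is a library, coloured by treatment, and axes give the share of variance. The first component orders vehicle, AA and PGE2 at both days, and vehicle replicate 4 of day 6 lies apart from its group.

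The first comparison asked how organoids responded within 1 day of AA. Lgr5 (ENSMUSG00000020140.15), the R-spondin receptor that marks crypt base columnar stem cells, went from 26.7 ± 0.627 to 6.91 ± 0.985 CPM (mean ± SD, n = 3 per group; log2 fold change -1.94 ± 0.13, SE; 3.84-fold lower, adjusted p = 4.6e-12), and Olfm4, a secreted glycoprotein of the same cells, from 87.7 ± 7.06 to 26.4 ± 1.00 CPM (log2 fold change -1.73 ± 0.11). Genes of fetal-like or regenerating epithelium went the other way: Msln, a surface glycoprotein of mesothelial and fetal epithelium, rose from 88.7 ± 3.53 to 460 ± 19.8 CPM (2.37 ± 0.05, adjusted p = 3.6e-24), Clu, a secreted chaperone made by revival stem cells, from 50.9 ± 4.06 to 186 ± 7.59 CPM (1.87 ± 0.09), and Ly6a, the surface antigen Sca-1, from 55.4 ± 2.63 to 158 ± 5.18 CPM (1.52 ± 0.08). The desaturases Fads1 and Fads2, which make AA from linoleic acid, fell by 1.63 and 1.26 on the log2 scale, and Ptgs2, the cyclooxygenase that starts prostaglandin synthesis, rose 6.85-fold to 23.7 ± 2.20 CPM.

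Of the 19 tested members of the crypt base columnar stem cell list, 3 rose, 12 fell and 4 were not called, with falls of Rgmb, a BMP co-receptor (-1.24 ± 0.06), and Smoc2, a matrix protein (-1.39 ± 0.06). 15 were called adjusted over the list alone (median log2 fold change -0.61, list adjusted p = 6.4e-05). Of the 19 members of the fetal-like and regenerative epithelium list, 16 rose, 0 fell and 3 were not called, among them Areg, an EGF receptor ligand (1.84 ± 0.06), and Anxa3, an annexin (1.67 ± 0.06). With 17 called adjusted over the list alone, the median was 1.67 (list adjusted p = 2.3e-16). Targets of YAP/TEAD, the transcription pair active in wounded epithelium, rose as well: of 15, 13 rose, 1 fell and 1 was not called, with rises of F3, tissue factor (2.49 ± 0.08), and Ccn2, a matrix-associated growth factor (2.08 ± 0.11). 14 were called adjusted over the list alone (median 1.07, list adjusted p = 6.6e-10). In the cAMP/CREB early response list, whose members answer to receptors that raise cAMP, 7 rose, 0 fell and 11 were not called, including Fos (1.34 ± 0.08) and Dusp1, a phosphatase of MAP kinases (2.35 ± 0.17). With 7 called adjusted over the list alone, the median was 0.77 (list adjusted p = 1.5e-04). Axin2, a feedback inhibitor of Wnt signalling, fell (-0.86 ± 0.05) while the Wnt target Ccnd1, cyclin D1, rose (0.47 ± 0.05), and the Wnt target list was not called: 3 higher, 5 lower and 6 not called of 14, 8 adjusted over the list alone (median -0.06, list adjusted p = 0.237).

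Lipid genes moved in opposite directions by pathway at day 1 of AA. In the fatty acid synthesis and desaturation list 1 rose, 13 fell and 3 were not called, with Scd2, a stearoyl-CoA desaturase, falling from 1595 ± 34.7 to 581 ± 24.8 CPM. A total of 15 were called adjusted over the list alone (median -0.54, list adjusted p = 1.3e-06, adjusted p = 0.175 with an estimated correlation). In the fatty acid oxidation and PPAR target list 15 rose, 3 fell and 6 were not called, with rises of Plin2, a lipid droplet coat protein (1.10 ± 0.06), and Angptl4, a lipoprotein lipase inhibitor (1.40 ± 0.08). With 18 called adjusted over the list alone, the median was 0.25 (list adjusted p = 3.5e-04, adjusted p = 0.31 with an estimated correlation). The cholesterol synthesis list went lower, 2 higher, 14 lower and 6 not called of 22, 17 adjusted over the list alone (median -0.20, list adjusted p = 2.5e-04, adjusted p = 0.31 with an estimated correlation), with Dhcr7, a late enzyme of the pathway, at -0.74 ± 0.06. Among NRF2 and oxidative stress genes 8 rose, 2 fell and 6 were not called, led by Slc7a11, the cystine importer (1.11 ± 0.05). 11 were called adjusted over the list alone (median 0.31, list adjusted p = 0.00522, adjusted p = 0.31 with an estimated correlation). The unfolded protein and integrated stress response list went lower, 1 higher, 11 lower and 5 not called of 17, 12 adjusted over the list alone (median -0.29, list adjusted p = 0.00314, adjusted p = 0.31 with an estimated correlation), although Atf3, a stress-induced transcription factor, rose (1.58 ± 0.14).

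Among cell type lists at day 1 of AA, in the Paneth cell list 0 rose, 5 fell and 10 were not called, with Lyz1, lysozyme, at -0.59 ± 0.08 and Itln1, a lectin, at -1.26 ± 0.09. With 8 called adjusted over the list alone, the median was -0.38 (list adjusted p = 0.0138, adjusted p = 0.375 with an estimated correlation). In the enterocyte list 11 rose, 3 fell and 8 were not called, with Alpi, intestinal alkaline phosphatase, at 0.74 ± 0.07. 15 were called adjusted over the list alone (median 0.21, list adjusted p = 0.0212, adjusted p = 0.45 with an estimated correlation). In the proliferation list, 1 rose, 10 fell and 12 were not called, and Mki67, the cycling-cell antigen, was not called (-0.11 ± 0.06). With 11 called adjusted over the list alone, the median was -0.11 (list adjusted p = 0.0212, adjusted p = 0.427 with an estimated correlation). The enteroendocrine cell list was not called, with 8 higher and 2 lower of 16 (list adjusted p = 0.0741), but Neurog3, the transcription factor of their progenitors, fell 3.81-fold. Chga, chromogranin A, rose (0.43 ± 0.15, adjusted p = 0.0211), a call lost without vehicle replicate 3 (0.34, adjusted p = 0.113) or without AA replicate 1 (0.38, adjusted p = 0.0810). Not called by camera were the goblet cell (2 higher, 7 lower of 13), tuft cell (2 and 0 of 8) and prostanoid and eicosanoid pathway (7 and 3 of 17) lists. The same held for the interferon response (3 and 0 of 10), antigen presentation (1 and 3 of 8), chromatin modifier (0 and 6 of 22), heat shock (5 and 2 of 10) and mitochondrially encoded (0 and 2 of 10) lists. The largest rises by the naming rule were those of Ankrd1, a muscle ankyrin repeat protein and YAP target (0.0755 to 2.01 CPM), Cnfn, a cornified envelope protein (0.128 to 2.03 CPM), Fst, an activin antagonist (3.41 ± 0.21), Tmem40 (3.39 ± 0.28), Il5ra, an interleukin receptor (3.38 ± 0.20), and Pbp2 (0.302 to 3.20 CPM). By edgeR 6197 of 14850 genes were called, 2894 higher and 3303 lower, and 1069 changed at least 2-fold, 836 of them higher. The balance of directions turned with a stricter filter (3075 higher, 2826 lower), without rRNA-like and mitochondrial genes (3152 and 2749) and with only the groups in the contrast (3258 and 3089). Among named genes called, B2m alone did not have every treated library on the same side of every vehicle library.

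**Figure D2:**
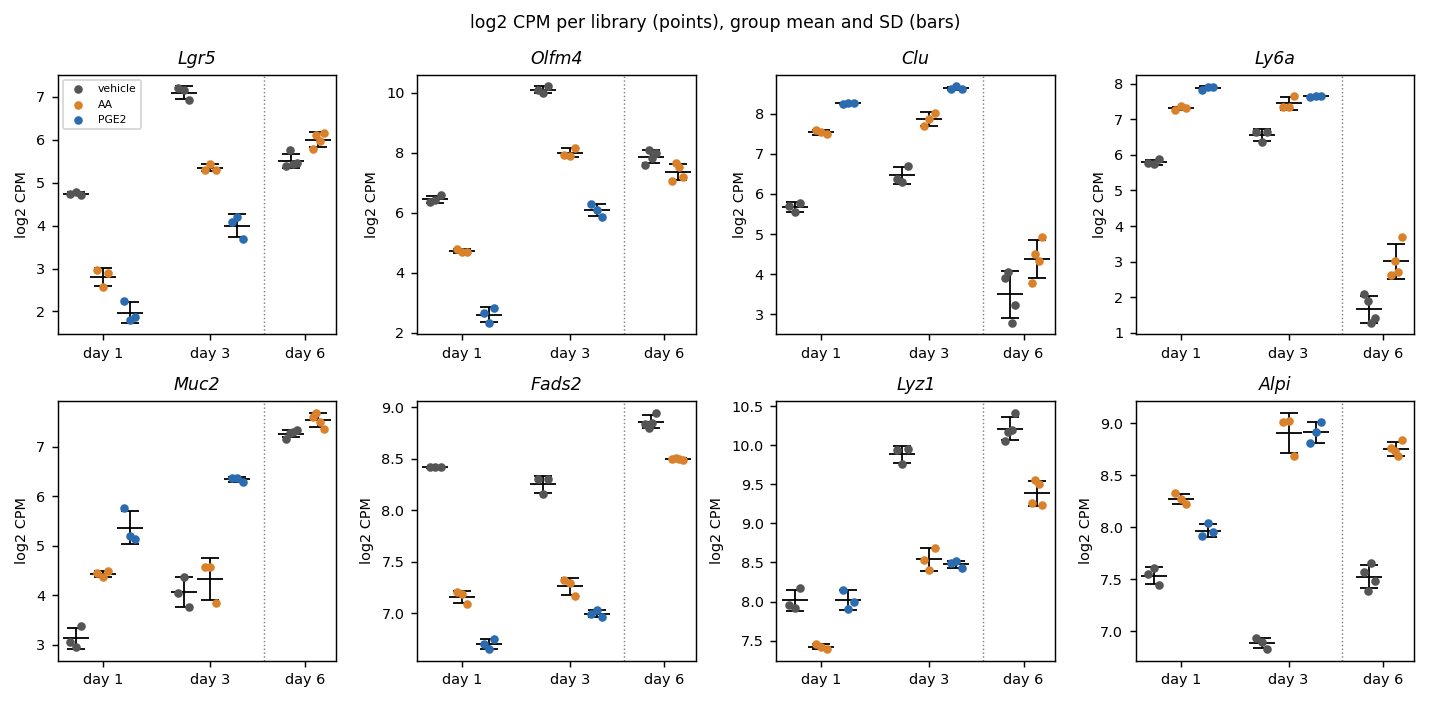
Log2 CPM of Lgr5, Olfm4, Clu, Ly6a, Muc2, Fads2, Lyz1 and Alpi in each library by treatment and day; points are libraries and bars are the mean and SD of a group. Lgr5 and Olfm4 lie below vehicle with AA and PGE2 at days 1 and 3, and Lgr5 lies above vehicle with AA at day 6.

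At day 3 of AA the stem cell and fetal-like changes were still present and Paneth and enteroendocrine genes had fallen. Lgr5 went from 137 ± 13.7 to 40.5 ± 2.32 CPM (n = 3 per group, log2 fold change -1.77 ± 0.08, adjusted p = 1.5e-14) and Olfm4 from 1100 ± 88.6 to 257 ± 26.2 CPM (-2.09 ± 0.09), while Msln rose from 106 ± 4.48 to 456 ± 26.5 CPM (2.10 ± 0.05, adjusted p = 9.6e-23). Lyz1 fell by 1.34 on the log2 scale and Chgb, a granin of endocrine granules, went from 85.2 ± 6.24 to 33.1 ± 3.65 CPM (-1.35 ± 0.09). Alpi rose from 118 ± 4.29 to 484 ± 61.7 CPM (2.03 ± 0.07, adjusted p = 4.1e-16). Isx, a homeobox repressor of retinoid and carotenoid uptake, rose from 1.07 ± 0.220 to 21.6 ± 3.49 CPM (4.33 ± 0.20), and Tek, the angiopoietin receptor, from 0.162 to 5.72 CPM.

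In the crypt base columnar stem cell list at day 3, 0 rose, 14 fell and 5 were not called, with Mex3a, an RNA-binding protein of slow-cycling crypt cells, at -1.60 ± 0.08. A total of 14 were called adjusted over the list alone (median -0.82, list adjusted p = 1.5e-10). In the fetal-like and regenerative epithelium list, 16 rose, 0 fell and 3 were not called, including Il33, an alarmin cytokine (2.72 ± 0.13), and S100a6 (1.40 ± 0.07). With 17 called adjusted over the list alone, the median was 1.20 (list adjusted p = 1.0e-12). Of YAP/TEAD targets, 8 rose, 0 fell and 7 were not called. 9 were called adjusted over the list alone (median 0.49, list adjusted p = 0.00412). Wnt targets were now called lower, 2 higher, 9 lower and 3 not called of 14, 11 adjusted over the list alone (median -0.39, list adjusted p = 0.00323), with Prox1, a transcription factor, at -1.86 ± 0.20. In the Paneth cell list 0 rose, 14 fell and 1 was not called, with Mmp7, the protease that activates alpha-defensins, at -1.66 ± 0.09 and Defa30 at -2.10 ± 0.09, a value that is uncertain because Defa paralogs share sequence. With 14 called adjusted over the list alone, the median was -1.65 (list adjusted p = 1.1e-10). In the enteroendocrine cell list 1 rose, 13 fell and 2 were not called, with Chga at -1.61 ± 0.13 and Cck, cholecystokinin, at -1.30 ± 0.15. 14 were called adjusted over the list alone (median -1.20, list adjusted p = 4.5e-06).

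In the enterocyte list at day 3 of AA 18 rose, 1 fell and 3 were not called, with Apoa1, an apolipoprotein of chylomicrons, at 1.29 ± 0.06 and Krt20, a keratin of differentiated cells, at 1.41 ± 0.07. With 20 called adjusted over the list alone, the median was 0.77 (list adjusted p = 3.0e-10, adjusted p = 0.0638 with an estimated correlation). In the fatty acid oxidation and PPAR target list 20 rose, 1 fell and 3 were not called, with Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, at 0.99 ± 0.06 and Vnn1, a pantetheinase, at 1.84 ± 0.11. A total of 22 were called adjusted over the list alone (median 0.67, list adjusted p = 7.8e-10). Of fatty acid synthesis and desaturation genes, 3 rose, 11 fell and 3 were not called, with Fads1 (ENSMUSG00000010663.5) at -1.53 ± 0.06 but Me1, malic enzyme, at 1.03 ± 0.05. With 17 called adjusted over the list alone, the median was -0.38 (list adjusted p = 0.0019, adjusted p = 0.305 with an estimated correlation). In the NRF2 and oxidative stress list 14 rose, 0 fell and 2 were not called, with Nqo1, a quinone reductase, at 1.08 ± 0.06. 15 were called adjusted over the list alone (median 0.72, list adjusted p = 7.6e-10). In the prostanoid and eicosanoid pathway list, 6 rose, 1 fell and 10 were not called, with Ptges, a PGE2 synthase, rising from 1.04 ± 0.543 to 5.74 ± 1.34 CPM and Cyp4f14, which hydroxylates leukotrienes, at 1.12 ± 0.06. With 7 called adjusted over the list alone, the median was 0.20 (list adjusted p = 0.0391, adjusted p = 0.0779 with an estimated correlation). Of chromatin modifiers, 0 rose, 10 fell and 12 were not called, with Dnmt1, the maintenance DNA methyltransferase, at -0.41 ± 0.05 and Ezh2, the methyltransferase of the Polycomb complex, at -0.37 ± 0.05. 10 were called adjusted over the list alone (median -0.17, list adjusted p = 0.00506, adjusted p = 0.299 with an estimated correlation). In the heat shock list 4 rose, 0 fell and 6 were not called, including Hspa1b, an inducible chaperone (1.04 ± 0.12). With 4 called adjusted over the list alone, the median was 0.12 (list adjusted p = 0.0329, adjusted p = 0.317 with an estimated correlation).

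Lists not called at day 3 of AA were proliferation (3 higher and 8 lower of 23), goblet cell (2 and 4 of 13), tuft cell (2 and 1 of 8) and cAMP/CREB early response (7 and 2 of 18). So were cholesterol synthesis (10 and 3 of 22), unfolded protein and integrated stress response (5 and 5 of 17), interferon response (3 and 0 of 10), antigen presentation (1 and 3 of 8) and mitochondrially encoded (0 and 0 of 10). Mki67 was -0.17 ± 0.06 with a call (adjusted p = 0.018) that was lost without vehicle replicate 3 (-0.16, adjusted p = 0.0656) or without AA replicate 3 (-0.07, adjusted p = 0.271). By edgeR 6129 of 14850 genes were called, 3143 higher and 2986 lower. This split depended on the scaling: with total counts alone, 2459 were higher and 3903 lower. At least 2-fold changes numbered 1143, of which 633 were higher. Among named genes called, libraries of the groups overlapped in B2m and Hsp90aa1.

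Organoids given PGE2 itself were compared with vehicle to measure the response to the prostaglandin alone, at 50 nM against 25 µM for AA. At day 1, Lgr5 went from 26.7 ± 0.627 to 3.81 ± 0.670 CPM (n = 3 per group, log2 fold change -2.78 ± 0.15, adjusted p = 3.7e-14) and Olfm4 from 87.7 ± 7.06 to 6.01 ± 1.03 CPM (-3.85 ± 0.15). Il33 rose from 2.99 ± 0.843 to 101 ± 2.03 CPM (5.08 ± 0.11, adjusted p = 2.6e-26), Msln from 88.7 ± 3.53 to 902 ± 22.9 CPM (3.35 ± 0.05) and Mucl3, a mucin-like protein, from 0.578 ± 0.0345 to 43.4 ± 0.429 CPM (6.21 ± 0.16). Slc16a12, a creatine transporter, went from 15.3 ± 2.08 to 0.558 ± 0.203 CPM.

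With PGE2 at day 1, in the crypt base columnar stem cell list, 4 rose, 13 fell and 2 were not called, with Msi1, an RNA-binding protein, at -2.77 ± 0.11 and Smoc2 at -2.80 ± 0.07. A total of 18 were called adjusted over the list alone (median -0.62, list adjusted p = 0.0011, adjusted p = 0.121 with an estimated correlation). In the fetal-like and regenerative epithelium list 18 rose, 0 fell and 1 was not called, with Cd55, a complement regulator, at 2.52 ± 0.06 and Anxa3 at 2.35 ± 0.06. With 18 called adjusted over the list alone, the median was 2.35 (list adjusted p = 2.5e-13). Of YAP/TEAD targets, 14 rose, 1 fell and 0 were not called, with F3 at 3.19 ± 0.08. 15 were called adjusted over the list alone (median 1.83, list adjusted p = 4.9e-08). In the cAMP/CREB early response list 15 rose, 1 fell and 2 were not called, with Dusp1 at 3.93 ± 0.15 and Nr4a1, an orphan nuclear receptor, at 2.60 ± 0.10. With 16 called adjusted over the list alone, the median was 1.26 (list adjusted p = 1.4e-05). In the goblet cell list, 9 rose, 2 fell and 2 were not called, with Muc2, the gel-forming mucin, at 2.29 ± 0.23 and Clca1, a secreted mucus protease, at 1.65 ± 0.09. 11 were called adjusted over the list alone (median 0.38, list adjusted p = 0.0379, adjusted p = 0.518 with an estimated correlation). In the enteroendocrine cell list 10 rose, 2 fell and 4 were not called, with Reg4 at 1.91 ± 0.12 but Neurog3 at -2.87 ± 0.19. With 13 called adjusted over the list alone, the median was 0.75 (list adjusted p = 0.0474, adjusted p = 0.536 with an estimated correlation).

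Of fatty acid synthesis and desaturation genes, 2 rose, 12 fell and 3 were not called, with Fads1 at -2.38 ± 0.06. A total of 14 were called adjusted over the list alone (median -0.39, list adjusted p = 0.0011, adjusted p = 0.499 with an estimated correlation). In the cholesterol synthesis list 4 rose, 14 fell and 4 were not called, with Tm7sf2, a sterol reductase, at -1.42 ± 0.07. With 18 called adjusted over the list alone, the median was -0.20 (list adjusted p = 0.0379, adjusted p = 0.649 with an estimated correlation). In the unfolded protein and integrated stress response list, 1 rose, 10 fell and 6 were not called, with Phgdh, the first enzyme of serine synthesis, at -0.84 ± 0.06. 13 were called adjusted over the list alone (median -0.28, list adjusted p = 0.0132, adjusted p = 0.528 with an estimated correlation). Fatty acid oxidation and PPAR target genes were not called as a list, 5 higher, 14 lower and 5 not called of 24, 19 adjusted over the list alone (median -0.27, list adjusted p = 0.13), with Acot1, an acyl-CoA thioesterase, at -2.18 ± 0.08, Fabp1, the fatty acid binding protein, at -1.90 ± 0.10 and Angptl4 at 1.63 ± 0.08. Nor were the enterocyte (6 higher and 12 lower of 22), Paneth cell (7 and 3 of 15), Wnt target (3 and 5 of 14) or proliferation (4 and 9 of 23) lists. Tuft cell (3 and 0 of 8), prostanoid and eicosanoid pathway (6 and 5 of 17) and NRF2 and oxidative stress (8 and 3 of 16) genes were not called as lists. Also uncalled were the interferon response (5 and 1 of 10), antigen presentation (2 and 3 of 8), chromatin modifier (1 and 8 of 22), heat shock (5 and 2 of 10) and mitochondrially encoded (0 and 1 of 10) lists. Within the prostanoid list, Ptgs2 rose (3.42 ± 0.12), as did Slco2a1, the prostaglandin importer (2.70 ± 0.17). By edgeR 8306 of 14850 genes were called, 4015 higher and 4291 lower, and 2159 changed at least 2-fold, 1420 of them higher. With total counts alone 3378 were higher and 5175 lower, and with only the groups in the contrast 4199 and 4098. Libraries of the groups overlapped in H2-K1 alone among named genes called.

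At day 3 of PGE2, genes of the stomach lining were among the largest rises: Gkn1, gastrokine, went from 0.0793 to 18.9 CPM and Tff1, the gastric trefoil peptide, from 0.469 ± 0.268 to 32.6 ± 1.13 CPM (n = 3 per group, log2 fold change 6.16 ± 0.20, adjusted p = 1.1e-21). Tek went from 0.162 ± 0.0626 to 35.1 ± 2.14 CPM and Dsg3, a desmosomal cadherin of stratified epithelium, from 2.08 ± 0.505 to 63.5 ± 2.58 CPM (4.92 ± 0.11). Lgr5 went from 137 ± 13.7 to 16.0 ± 2.84 CPM (-3.11 ± 0.09, adjusted p = 4.6e-19), and Igfbp4, an IGF-binding protein of crypt base cells, from 42.1 ± 6.53 to 2.94 ± 0.396 CPM (-3.84 ± 0.13). Zg16, a lectin of goblet cell granules, rose from 2.63 ± 0.230 to 63.7 ± 2.48 CPM (4.58 ± 0.15).

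In the crypt base columnar stem cell list at day 3 of PGE2, 3 rose, 14 fell and 2 were not called. With 17 called adjusted over the list alone, the median was -0.84 (list adjusted p = 1.0e-05). Of fetal-like and regenerative epithelium genes, 18 rose, 0 fell and 1 was not called, with Il33 at 4.85 ± 0.11 and Ecm1, a matrix protein, at 2.67 ± 0.11. 18 were called adjusted over the list alone (median 1.91, list adjusted p = 1.6e-11). In the YAP/TEAD target list 11 rose, 0 fell and 4 were not called. With 11 called adjusted over the list alone, the median was 1.01 (list adjusted p = 8.8e-05). Of Wnt targets, 3 rose, 8 fell and 3 were not called, with Tcf7, a Wnt-responsive transcription factor, at -1.02 ± 0.11. A total of 11 were called adjusted over the list alone (median -0.57, list adjusted p = 0.0297, adjusted p = 0.0843 with an estimated correlation). In the proliferation list, 0 rose, 20 fell and 3 were not called, with Top2a, topoisomerase II, at -0.76 ± 0.05 and Mki67 at -0.40 ± 0.06. With 20 called adjusted over the list alone, the median was -0.40 (list adjusted p = 1.5e-06, adjusted p = 0.111 with an estimated correlation). In the cAMP/CREB early response list 12 rose, 2 fell and 4 were not called. 14 were called adjusted over the list alone (median 0.74, list adjusted p = 0.00107). Of interferon response genes, 7 rose, 0 fell and 3 were not called, with Irf7, the interferon regulator, at 2.11 ± 0.15 and Mx1, an antiviral GTPase, at 2.72 ± 0.22. With 7 called adjusted over the list alone, the median was 0.90 (list adjusted p = 0.00419). In the prostanoid and eicosanoid pathway list 10 rose, 3 fell and 4 were not called, with Slco2a1 at 3.10 ± 0.14. 13 were called adjusted over the list alone (median 0.65, list adjusted p = 0.00595).

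In the Paneth cell list at day 3 of PGE2 1 rose, 13 fell and 1 was not called, with Lyz1 at -1.41 ± 0.07. With 14 called adjusted over the list alone, the median was -2.13 (list adjusted p = 1.5e-06, adjusted p = 0.0799 with an estimated correlation). Of enteroendocrine cell genes, 1 rose, 13 fell and 2 were not called, with Tac1, the precursor of substance P, at -2.41 ± 0.17 and Chga at -1.48 ± 0.12. A total of 14 were called adjusted over the list alone (median -1.51, list adjusted p = 4.1e-04, adjusted p = 0.111 with an estimated correlation). In the goblet cell list 8 rose, 1 fell and 4 were not called, with Muc2 at 2.27 ± 0.19. With 10 called adjusted over the list alone, the median was 1.00 (list adjusted p = 0.00147, adjusted p = 0.119 with an estimated correlation). Of enterocyte genes, 15 rose, 4 fell and 3 were not called, with Apoa1 at 2.16 ± 0.05 and Alpi at 2.03 ± 0.07. 20 were called adjusted over the list alone (median 0.62, list adjusted p = 4.7e-04, adjusted p = 0.286 with an estimated correlation). In the tuft cell list, not called, 3 of 8 were higher and 1 lower (list adjusted p = 0.292), and Avil, an actin-severing protein of tuft cells, rose (3.57 ± 0.15).

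Of fatty acid oxidation and PPAR target genes at day 3 of PGE2, 14 rose, 5 fell and 5 were not called, with Acot1 at -2.13 ± 0.08. With 19 called adjusted over the list alone, the median was 0.27 (list adjusted p = 0.0358, adjusted p = 0.409 with an estimated correlation). In the fatty acid synthesis and desaturation list 3 rose, 11 fell and 3 were not called. 14 were called adjusted over the list alone (median -0.25, list adjusted p = 0.0135, adjusted p = 0.393 with an estimated correlation). Of NRF2 and oxidative stress genes, 12 rose, 2 fell and 2 were not called. With 14 called adjusted over the list alone, the median was 0.41 (list adjusted p = 0.00186, adjusted p = 0.201 with an estimated correlation). Of chromatin modifiers, 1 rose, 10 fell and 11 were not called, with Dnmt3a, a de novo DNA methyltransferase, at -1.05 ± 0.07 and Ezh2 at -0.61 ± 0.05. A total of 11 were called adjusted over the list alone (median -0.15, list adjusted p = 0.00898, adjusted p = 0.286 with an estimated correlation). The cholesterol synthesis (5 higher and 6 lower of 22), unfolded protein and integrated stress response (4 and 10 of 17), antigen presentation (2 and 2 of 8), heat shock (4 and 4 of 10) and mitochondrially encoded (0 and 2 of 10) lists were not called. By edgeR 8752 of 14850 genes were called, 4287 higher and 4465 lower, and 2194 changed at least 2-fold, 1416 of them higher. With only the groups in the contrast the balance turned, to 4176 higher and 3956 lower.

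**Figure D3:**
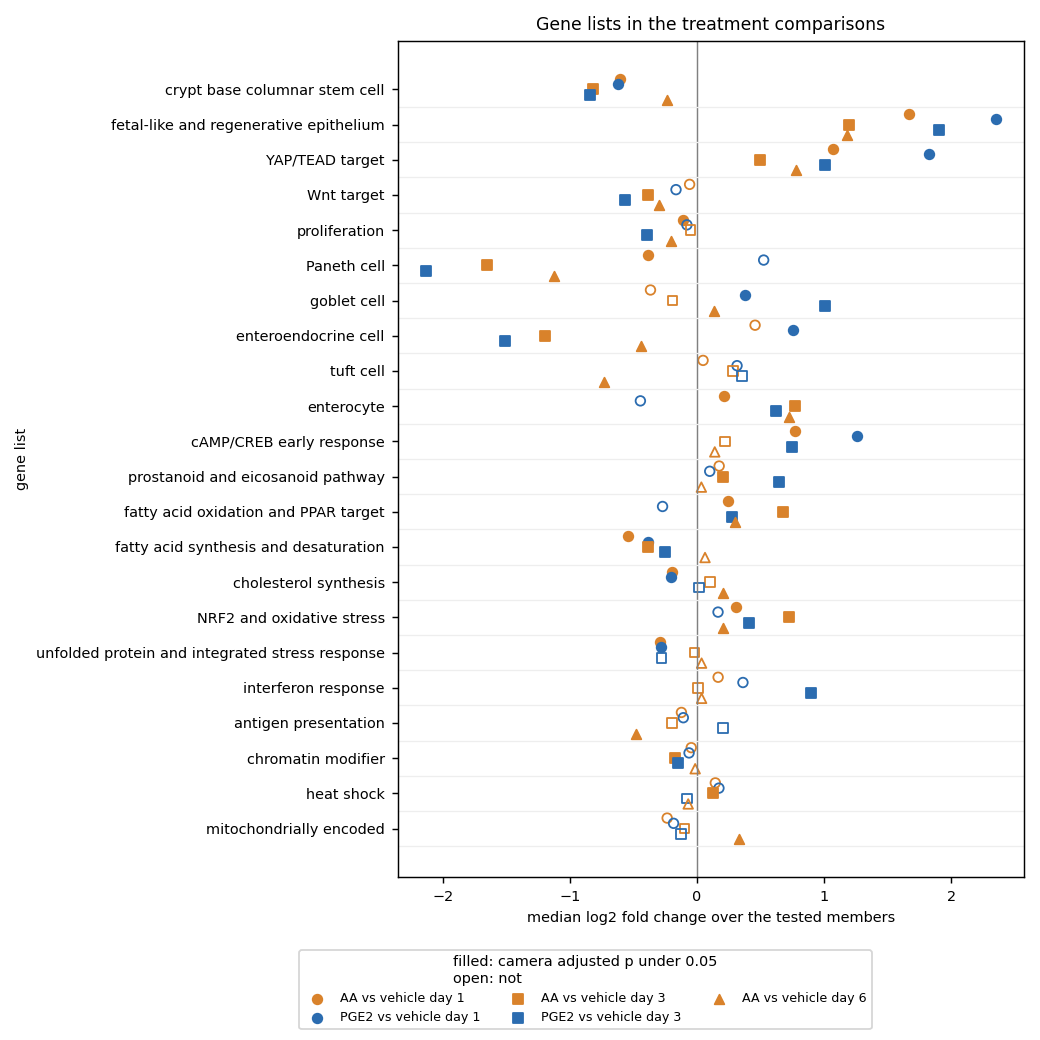
Median log2 fold change of the tested members of 22 gene lists in the 5 treatment against vehicle comparisons; filled points mark lists whose camera adjusted p was under 0.05. Fetal-like and regenerative epithelium genes lie to the right and Paneth cell genes to the left in most comparisons, and the crypt base columnar stem cell median is below 0 in all 5.

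By day 6 of AA, the direction of Lgr5 was different from that at days 1 and 3: it went from 45.6 ± 5.61 to 64.2 ± 7.39 CPM (n = 4 per group, log2 fold change 0.49 ± 0.10, adjusted p = 0.00262), while Ascl2, a transcription factor of the same stem cells, went from 5.29 ± 0.866 to 2.94 ± 0.580 CPM (-0.84 ± 0.17) and Rgmb from 139 ± 14.1 to 83.7 ± 10.9 CPM (-0.73 ± 0.09). Olfm4 was -0.50 ± 0.13 (adjusted p = 0.0117), a call lost without vehicle replicate 4 (-0.47, adjusted p = 0.123). Sis, sucrase-isomaltase of the brush border, rose from 327 ± 68.8 to 1024 ± 180 CPM (1.64 ± 0.15) and Alpi from 185 ± 14.4 to 432 ± 20.3 CPM (1.23 ± 0.07, adjusted p = 5.8e-07). Lyz1 went from 1190 ± 126 to 673 ± 74.9 CPM (-0.82 ± 0.09). Nos2, inducible nitric oxide synthase, rose from 2.70 ± 0.264 to 16.8 ± 3.51 CPM (2.64 ± 0.17), and Slc7a2, a cationic amino acid transporter, went from 15.9 ± 0.335 to 3.34 ± 0.686 CPM (-2.25 ± 0.12).

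Of Paneth cell genes at day 6, 0 rose, 15 fell and 0 were not called, with Mmp7 at -0.79 ± 0.07 and Defa30, with the same uncertainty, at -2.01 ± 0.15. With 15 called adjusted over the list alone, the median was -1.12 (list adjusted p = 8.3e-11, adjusted p = 0.356 with an estimated correlation). In the enteroendocrine cell list, 0 rose, 11 fell and 6 were not called, with Gcg, proglucagon, at -1.32 ± 0.10. 13 were called adjusted over the list alone (median -0.44, list adjusted p = 4.4e-06, adjusted p = 0.243 with an estimated correlation). In the enterocyte list 14 rose, 1 fell and 7 were not called, with Slc5a1, the sodium-glucose cotransporter, at 1.09 ± 0.08. With 17 called adjusted over the list alone, the median was 0.72 (list adjusted p = 4.4e-06, adjusted p = 0.462 with an estimated correlation). Of fatty acid oxidation and PPAR target genes, 13 rose, 0 fell and 10 were not called, with Fabp1 at 1.66 ± 0.16 and Creb3l3, a transcription factor of lipid metabolism, at 1.23 ± 0.09. 15 were called adjusted over the list alone (median 0.30, list adjusted p = 3.3e-06, adjusted p = 0.451 with an estimated correlation). In the crypt base columnar stem cell list, 1 rose, 8 fell and 10 were not called. With 10 called adjusted over the list alone, the median was -0.24 (list adjusted p = 0.0187, adjusted p = 0.612 with an estimated correlation). Replicates spread as much as this median: AA replicate 1 lay below the other AA libraries in 19 of 19 members (median -0.30) and AA replicate 2 above in 19 of 19 (0.26). Of Wnt targets, 1 rose, 6 fell and 6 were not called. A total of 8 were called adjusted over the list alone (median -0.30, list adjusted p = 0.0213, adjusted p = 0.552 with an estimated correlation). Spread was as large here too: AA replicate 2 lay 0.31 above and AA replicate 1 0.27 below the other AA libraries, and vehicle replicate 4 0.20 above the other vehicle libraries. Of proliferation genes, 0 rose, 15 fell and 8 were not called, with Mcm6, a replicative helicase subunit, at -0.36 ± 0.05. With 16 called adjusted over the list alone, the median was -0.21 (list adjusted p = 7.9e-06, adjusted p = 0.356 with an estimated correlation).

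Of fetal-like and regenerative epithelium genes at day 6, 12 rose, 0 fell and 2 were not called, with Areg at 0.77 ± 0.07 and Anxa3 at 1.79 ± 0.19. 13 were called adjusted over the list alone (median 1.18, list adjusted p = 1.5e-06, adjusted p = 0.356 with an estimated correlation). Ly6a rose from 3.15 ± 0.845 to 8.29 ± 3.10 CPM (1.39 ± 0.25), and Anxa1 was not called (1.13 ± 0.43, adjusted p = 0.0745). The call of Clu (0.85 ± 0.28, adjusted p = 0.0372) was lost without vehicle replicate 3 (0.66, adjusted p = 0.0658) or 4 (0.76, adjusted p = 0.222) and without AA replicate 2 (0.83, adjusted p = 0.0719), 3 (0.89, adjusted p = 0.0572) or 4 (0.65, adjusted p = 0.0951). Of YAP/TEAD targets, 8 rose, 1 fell and 3 were not called, with Ereg, an EGF family ligand, at 1.14 ± 0.15. With 11 called adjusted over the list alone, the median was 0.78 (list adjusted p = 5.2e-04, adjusted p = 0.424 with an estimated correlation). In the goblet cell list 6 rose, 1 fell and 6 were not called, with Zg16 at 1.80 ± 0.16 and Clca1 at 1.86 ± 0.19. 7 were called adjusted over the list alone (median 0.13, list adjusted p = 0.0499, adjusted p = 0.49 with an estimated correlation). Vehicle replicate 4 lay 0.21 above and vehicle replicate 3 0.13 below the other vehicle libraries.

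In the tuft cell list, 0 rose, 4 fell and 4 were not called, with Dclk1, the kinase that marks tuft cells, going from 2.16 ± 0.877 to 0.839 ± 0.364 CPM (-1.36 ± 0.35). With 5 called adjusted over the list alone, the median was -0.73 (list adjusted p = 0.0346, adjusted p = 0.462 with an estimated correlation). In the antigen presentation list 0 rose, 6 fell and 5 were not called, with Psmb8, an immunoproteasome subunit, at -1.29 ± 0.11. A total of 6 were called adjusted over the list alone (median -0.48, list adjusted p = 0.00512, adjusted p = 0.462 with an estimated correlation). Of cholesterol synthesis genes, 9 rose, 0 fell and 13 were not called, with Sc5d at 0.49 ± 0.09. With 11 called adjusted over the list alone, the median was 0.21 (list adjusted p = 0.00189, adjusted p = 0.462 with an estimated correlation), with AA replicate 1 lying 0.14 above and AA replicate 2 0.19 below the other AA libraries. Of NRF2 and oxidative stress genes, 9 rose, 0 fell and 6 were not called, with Gclc, the enzyme that limits glutathione synthesis, at 0.39 ± 0.07. 11 were called adjusted over the list alone (median 0.21, list adjusted p = 0.0127, adjusted p = 0.356 with an estimated correlation). In the mitochondrially encoded list, 4 rose, 0 fell and 5 were not called. With 5 called adjusted over the list alone, the median was 0.33 (list adjusted p = 0.0187, adjusted p = 0.546 with an estimated correlation). Vehicle replicate 4 lay below the other vehicle libraries in 9 of 9 members (median -0.44), and vehicle replicate 3 above in 8 of 9 (0.25). In the other lists called, library medians lay nearer to the other libraries than the size of the list median. All 4 calls were lost without 1 library or more: without AA replicate 3, mt-Co1 was 0.30 (adjusted p = 0.0537), mt-Nd1 0.36 (0.0548), mt-Nd2 0.42 (0.0779) and mt-Nd6 0.46 (0.0831). Lists not called were cAMP/CREB early response (4 higher and 0 lower of 16), prostanoid and eicosanoid pathway (3 and 2 of 14) and fatty acid synthesis and desaturation (7 and 5 of 17). So were unfolded protein and integrated stress response (4 and 3 of 17), interferon response (0 and 2 of 9), chromatin modifier (3 and 8 of 22) and heat shock (3 and 2 of 9). Fads1 was lower (-0.64 ± 0.05) and Fads2 as well (-0.36 ± 0.05). By edgeR 4507 of 14663 genes were called, 2237 higher and 2270 lower, and 396 changed at least 2-fold, 258 of them higher. With RLE scaling this turned to 2303 higher and 2190 lower. Libraries of the groups overlapped in 7 named genes called, among them Fos, Clu, Olfm4, Abcc4, Cd74 and mt-Nd6. With an estimated correlation camera called 0 of 24 lists at day 6, with 3 at an unadjusted p under 0.05, and fry called 14, so the day 6 list results rest on the preset correlation.

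Marker lists of other cell types had few members above the filter. Of 12 fibroblast and smooth muscle markers, 2 were tested at days 1 and 3, with 1 or both called in each treatment comparison, and 2 at day 6, with 0 called. Of 12 immune cell markers 2 were tested at days 1 and 3, with 0 called at day 1 of AA or PGE2 and 1 higher at day 3 of each, and 1 at day 6, with 0 called. Of 10 endothelial and neural markers 3 were tested at days 1 and 3, with 1 to 3 called per comparison, and 2 at day 6, with 0 called. With PGE2 at day 3, Tubb3, a neuronal tubulin, went from 2.17 to 1.07 CPM. These lists were not called by camera in any treatment comparison where they could be tested.

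The overlap of the AA and PGE2 responses was measured next, at doses that differed (25 µM against 50 nM). Across 14850 genes the log2 fold changes at day 1 had a Pearson's r of 0.883 and a Spearman's rho of 0.843, and at day 3 an r of 0.842 and a rho of 0.774; genes are not independent replicates. At day 1, 2682 genes were higher with both, where the sizes of the calls alone would give 782, and 2873 were lower with both, against 954. At day 3 the numbers were 2677 (against 907) and 2442 (against 898). Opposite calls numbered 44 at day 1 and 123 at day 3. Among the genes called in the same direction, the change with PGE2 was the larger in size in 88.4% of 5555 at day 1 and in 79.0% of 5119 at day 3. Both responses subtract the same 3 vehicle libraries, and simulated draws with no treatment effect gave correlations of up to 0.517 at day 1 and 0.545 at day 3.

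**Figure D4:**
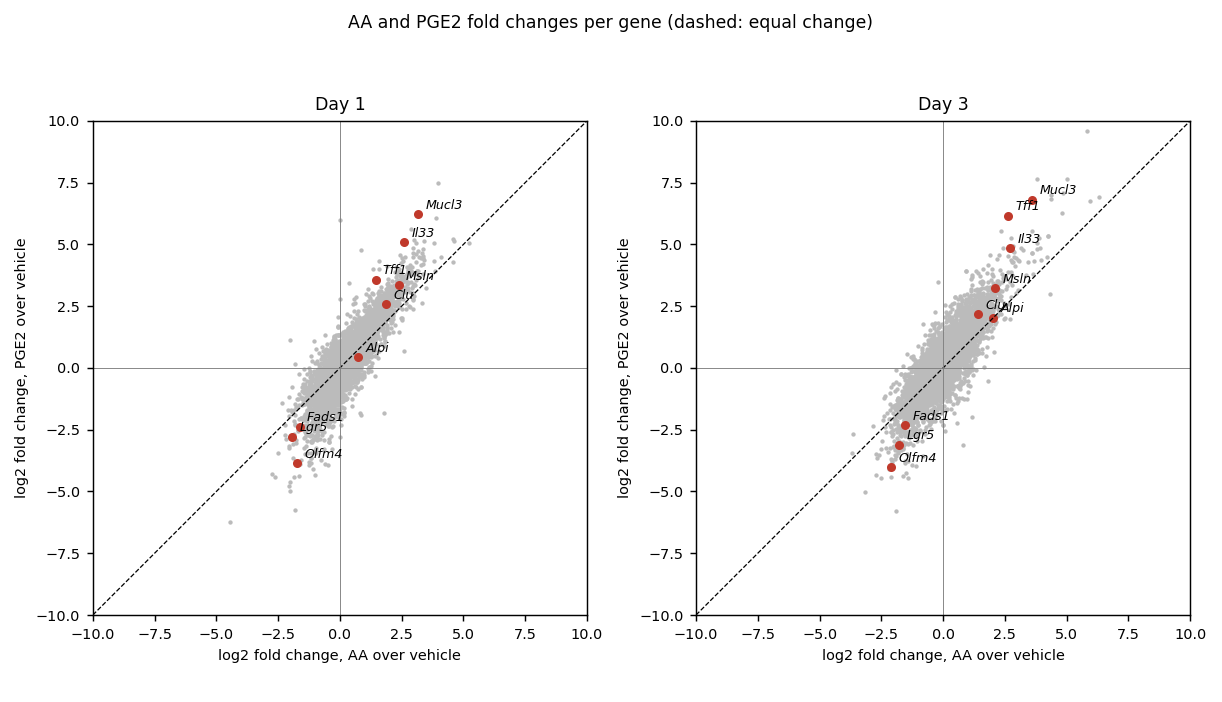
Log2 fold change with AA (horizontal) against that with PGE2 (vertical), each against vehicle, at days 1 and 3; each point is 1 of 14850 genes and labelled genes are named in the text. Of the genes called in the same direction at day 1, 88.4% have the larger change with PGE2.

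A direct test of AA against PGE2 asked which genes differed between the treatments at these doses. Mucl3 was lower with AA at day 1 (n = 3 per group, log2 difference -3.05 ± 0.10, adjusted p = 4.3e-20) and at day 3 (-3.19 ± 0.09), as were Ttyh1, a membrane channel protein (-3.10 ± 0.23 and -3.70 ± 0.23), and, at day 3, Tff1 (-3.52 ± 0.14). Of the genes higher with both at day 1, 1616 were lower with AA than with PGE2 and 24 higher; at day 3 these numbers were 1450 and 117. All 44 and 123 genes called in opposite directions also differed in the direct test. AA called 598 genes at day 1 that PGE2 did not, of which 147 differed between the treatments, and 887 at day 3, of which 413 differed.

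By lists, fatty acid oxidation and PPAR target genes gave, for AA against PGE2 at day 1, 17 higher, 1 lower and 6 not called of 24, 21 adjusted over the list alone (median 0.51, list adjusted p = 2.4e-11). Enterocyte genes gave 14 higher, 3 lower and 5 not called of 22, 17 adjusted over the list alone (median 0.55, list adjusted p = 1.6e-06, adjusted p = 0.199 with an estimated correlation). Stem cell genes of the crypt base gave 10 higher, 3 lower and 6 not called of 19, 15 adjusted over the list alone (median 0.27, list adjusted p = 2.2e-04, adjusted p = 0.0589 with an estimated correlation). Fetal-like and regenerative epithelium genes were lower with AA, at 0 higher, 16 lower and 3 not called of 19, 17 adjusted over the list alone (median -0.72, list adjusted p = 6.9e-12). YAP/TEAD target genes were lower too, at 1 higher, 11 lower and 3 not called of 15, 13 adjusted over the list alone (median -0.59, list adjusted p = 2.9e-06). cAMP/CREB early response genes gave 1 higher, 10 lower and 7 not called of 18, 12 adjusted over the list alone (median -0.47, list adjusted p = 4.6e-05). Paneth cell genes gave 0 higher, 10 lower and 5 not called of 15, 10 adjusted over the list alone (median -0.81, list adjusted p = 1.4e-05, adjusted p = 0.144 with an estimated correlation). By edgeR 4119 genes differed at day 1, 1671 higher with AA and 2448 lower, but with scaling by total counts 2570 were higher and 1746 lower, so the balance of directions rested on the scaling.

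At day 3 of AA against PGE2, fatty acid oxidation and PPAR target genes gave 15 higher, 3 lower and 6 not called of 24, 18 adjusted over the list alone (median 0.25, list adjusted p = 6.4e-05, adjusted p = 0.153 with an estimated correlation). Proliferation genes gave 21 higher, 0 lower and 2 not called of 23, 23 adjusted over the list alone (median 0.33, list adjusted p = 2.2e-11). Crypt base stem cell genes gave 11 higher, 4 lower and 4 not called of 19, 15 adjusted over the list alone (median 0.23, list adjusted p = 0.00894, adjusted p = 0.153 with an estimated correlation). Fetal-like genes were lower with AA, at 0 higher, 17 lower and 2 not called of 19, 17 adjusted over the list alone (median -0.83, list adjusted p = 2.9e-09, adjusted p = 0.0744 with an estimated correlation). YAP/TEAD targets gave 0 higher, 12 lower and 3 not called of 15, 12 adjusted over the list alone (median -0.49, list adjusted p = 6.3e-05). Goblet cell genes were at 0 higher, 12 lower and 1 not called of 13, 12 adjusted over the list alone (median -1.17, list adjusted p = 1.2e-08). Early response genes of cAMP/CREB gave 1 higher, 11 lower and 6 not called of 18, 14 adjusted over the list alone (median -0.60, list adjusted p = 4.0e-05). Enterocyte genes did not differ as a list, with 10 higher and 8 lower of 22. By edgeR 5711 genes differed at day 3, 2695 higher with AA and 3016 lower. This balance turned with RLE scaling (2996 and 2763), without a filter (3178 and 2497), with a stricter filter (3138 and 2640) and without rRNA-like and mitochondrial genes (3078 and 2689), and widened with total counts alone (2095 and 3373).

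Vehicle organoids at day 3 were compared with those at day 1 to show the changes that culture time alone brought. Olfm4 rose from 87.7 ± 7.06 to 1100 ± 88.6 CPM (n = 3 per group, log2 fold change 3.65 ± 0.10, adjusted p = 5.3e-14) and Slc16a3, a lactate exporter, from 1.77 ± 0.635 to 80.3 ± 16.8 CPM (5.49 ± 0.30). Upk3b, a uroplakin, was at 0.0260 CPM at day 1, near no counts, and at 3.52 CPM at day 3. Mt4, a metallothionein of stratified epithelium, went from 6.53 ± 0.664 to 1.44 ± 0.451 CPM (-2.14 ± 0.19), and the fall of Gml2 was lost without vehicle day 1 replicate 1 (-1.71, adjusted p = 0.0646). All 15 tested Paneth cell genes rose (median 1.87, list adjusted p = 4.1e-14, 15 adjusted over the list alone). Enteroendocrine cell genes gave 13 higher, 0 lower and 3 not called of 16, 13 adjusted over the list alone (median 1.40, list adjusted p = 7.2e-08). Crypt base columnar stem cell genes gave 12 higher, 2 lower and 5 not called of 19, 15 adjusted over the list alone (median 0.31, list adjusted p = 1.8e-06). Proliferation genes gave 0 higher, 22 lower and 1 not called of 23, 23 adjusted over the list alone (median -0.39, list adjusted p = 1.0e-13). By edgeR 5982 genes were called, 2943 higher and 3039 lower at day 3, and 768 changed at least 2-fold, 725 of them higher. With a stricter filter 3094 were higher and 2757 lower, and with total counts alone 3726 and 2042, and the median of all genes was 0.10 on the log2 scale with that scaling against 0.04 with TMM, so directions here are relative to the TMM scaling.

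Differences of responses tested whether a treatment acted differently by day. For AA at day 3 minus day 1, Isx had a difference of 3.31 ± 0.51 (adjusted p = 1.9e-05) and Apoc3, an apolipoprotein, 1.87 ± 0.26. Thbs1, thrombospondin, had -2.96 ± 0.09 (adjusted p = 3.1e-20) and Creb5, a CREB family factor, -2.94 ± 0.28. The Paneth cell list gave 0 higher, 12 lower and 3 not called of 15, 13 adjusted over the list alone (median -1.21, list adjusted p = 7.2e-11). The enteroendocrine cell list gave 0 higher, 11 lower and 5 not called of 16, 13 adjusted over the list alone (median -1.32, list adjusted p = 1.5e-10). The YAP/TEAD target list gave 0 higher, 10 lower and 5 not called of 15, 11 adjusted over the list alone (median -0.73, list adjusted p = 7.3e-10). The enterocyte list gave 15 higher, 1 lower and 6 not called of 22, 18 adjusted over the list alone (median 0.58, list adjusted p = 7.2e-11, adjusted p = 0.0615 with an estimated correlation). The crypt base columnar stem cell list gave 0 higher, 11 lower and 8 not called of 19, 13 adjusted over the list alone (median -0.28, list adjusted p = 3.5e-05) although Lgr5 itself did not differ between the days (0.18, adjusted p = 0.477). By edgeR 2668 genes differed, 1487 with a positive difference and 1181 with a negative difference, but 986 and 1410 with total counts alone and 1228 and 1324 with a stricter filter.

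For PGE2 at day 3 minus day 1, Zg16 had a difference of 3.48 ± 0.27 (adjusted p = 7.3e-10) and Tek 3.63 ± 0.49, while Tph1, the serotonin-making hydroxylase, had -3.64 ± 0.33 and Tac1 -3.54 ± 0.27 (adjusted p = 2.4e-11). The difference of Gkn1 (3.35 ± 0.99, adjusted p = 0.0122), which was near 0 CPM in vehicle, was lost without vehicle day 1 replicate 1 (2.79, adjusted p = 0.136) or 3 (3.11, adjusted p = 0.0615). The Paneth cell list gave 0 higher, 13 lower and 2 not called of 15, 14 adjusted over the list alone (median -2.55, list adjusted p = 5.9e-14). The enteroendocrine cell list gave 1 higher, 13 lower and 2 not called of 16, 14 adjusted over the list alone (median -2.02, list adjusted p = 6.2e-10). The enterocyte list gave 18 higher, 0 lower and 4 not called of 22, 19 adjusted over the list alone (median 1.07, list adjusted p = 2.5e-16). The YAP/TEAD target list gave 1 higher, 12 lower and 2 not called of 15, 13 adjusted over the list alone (median -0.82, list adjusted p = 6.4e-08). The fatty acid oxidation and PPAR target list gave 15 higher, 1 lower and 8 not called of 24, 18 adjusted over the list alone (median 0.51, list adjusted p = 1.0e-07, adjusted p = 0.0589 with an estimated correlation). By edgeR 3592 genes differed, 1876 with a positive and 1716 with a negative difference, but 2221 and 1277 with total counts alone and 1608 and 2015 with a stricter filter.

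For AA at day 6 minus day 3, Lgr5 had a difference of 2.24 ± 0.14 (n = 3 and 4 per group, adjusted p = 1.1e-11), Nos2 2.41 ± 0.21 and Slc28a2, a nucleoside transporter, 2.65 ± 0.31. Reg3b, an antibacterial lectin, had -3.30 ± 0.33 (adjusted p = 1.0e-08). The differences of Ptges (-3.17 ± 0.82) and Prl2c3 (-4.22 ± 0.92) were for genes with group means under 0.2 CPM at day 6. The first was lost without vehicle day 6 replicate 3 (-2.63, adjusted p = 0.0611) and the second without vehicle day 6 replicate 4 (-2.84, adjusted p = 0.0970). The crypt base columnar stem cell list gave 11 higher, 1 lower and 7 not called of 19, 12 adjusted over the list alone (median 0.61, list adjusted p = 3.4e-08, adjusted p = 0.225 with an estimated correlation). The NRF2 and oxidative stress list gave 0 higher, 13 lower and 3 not called of 16, 14 adjusted over the list alone (median -0.49, list adjusted p = 9.2e-10). The Paneth cell list gave 4 higher, 0 lower and 11 not called of 15, 7 adjusted over the list alone (median 0.43, list adjusted p = 0.00972, adjusted p = 0.454 with an estimated correlation). By edgeR 2969 of 15504 genes differed, 1362 with a positive and 1607 with a negative difference, but 1747 and 1020 with total counts alone and 1490 and 1323 without a filter. Across 13949 genes tested at both days, the responses to AA at days 3 and 6 had an r of 0.536, with 1362 genes higher at both (the sizes of the calls alone would give 455), 1036 lower at both (against 467) and 143 in opposite directions. Between days 1 and 3 of AA the r was 0.607, with 1866 genes higher on both days and 1643 lower.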

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

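Tests of a smaller enterocyte share with PGE2 and the comparison of library content between days were chosen after the results were seen, and the other tests were written before. Values that stood apart are given first, and 3 patterns are then weighed.

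The response to treatment differed between days for many genes. For AA at day 3 minus day 1, 2668 genes differed, among them Ly6a (-0.63), Clu (-0.46), Anxa1 (-0.97), Ptgs2 (-1.64), Scd1 (0.91), Fads2 (0.27), Lyz1 (-0.75), Alpi (1.29) and Chga (-2.04) on the log2 scale. For PGE2 at day 3 minus day 1, 3592 genes differed, among them Ly6a (-1.01), Clu (-0.41), Anxa1 (-1.09), Ptgs2 (-1.27), Scd1 (0.70), Fads2 (0.46), Mki67 (-0.30), Lyz1 (-1.41), Alpi (1.60) and Chga (-2.36). For AA at day 6 minus day 3, 2969 genes differed, among them Lgr5 (2.24), Olfm4 (1.58), Ascl2 (-0.73), Scd1 (0.48), Fads2 (0.62), Lyz1 (0.51), Alpi (-0.82) and Chga (0.88). From day 1 to day 3 the rises of the fetal-like genes named here became smaller and that of Alpi larger. In differences involving day 6, the day could not be separated from library content, and the labels name no batch.

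Single libraries lay apart from the other libraries of their group in 9 of 218 tests, where chance alone gives about 1 in 20 (10.9). At day 6, these were Syt8 in vehicle replicate 1 (log2 CPM 0.24), Ereg (1.35), Junb (4.74) and Fads1 (8.43) in vehicle replicate 4, Defa17 in vehicle replicate 2 (8.92), Rbpms (3.14) and Itpkb (-1.44) in AA replicate 4 and Znrf3 in AA replicate 2 (5.58). The mitochondrial rRNA share of vehicle replicate 1 was 0.266%. By list, vehicle replicate 4 lay below the other vehicle libraries in mitochondrially encoded genes (9 of 9, median -0.44) and above them in Paneth cell genes (14 of 15, median 0.29), and AA replicates 1 and 2 lay below (median -0.30) and above (0.26) the other AA libraries in 19 of 19 stem cell genes. The cause was not tested. No library was left out for these values.

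Genes called with both AA and PGE2 mostly moved in the same direction, 5555 against 44 in opposite directions at day 1 and 5119 against 123 at day 3, while 598 and 887 genes were called with AA and not with PGE2. If noise in the shared vehicle libraries made this, the covariance of the responses would be near that of simulated draws. The lowest ratio over the 2 days was 16.0. Without a few abundant loci and with total-count scaling, the correlation was 0.844 at the lower of the days. Scaling moves all fold changes by nearly the same amount and leaves a correlation almost unchanged. Whether scaling shaped the calls in the same direction was thus not tested. Noise in the shared vehicle libraries was disfavoured, but a shift common to them was not tested. A shared response, such as conversion of AA to prostaglandins, is possible. Conversion was not tested, since no cyclooxygenase inhibitor was used.

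Fatty acid oxidation genes were higher with AA than with PGE2 under 3 scalings. List medians were 0.51 to 0.58 at day 1 (SE 0.26) and 0.21 to 0.28 at day 3 (SE 0.21). Each SE of a list median is over member genes, not libraries. The day 3 list call was lost with an estimated correlation (adjusted p = 0.153). A smaller enterocyte share with PGE2 goes with day 1, where the enterocyte list without fatty acid oxidation members was 0.52 (SE 0.17) higher with AA than with PGE2. At day 3 that list was 0.64 (SE 0.24) above vehicle with PGE2, which does not compare the treatments, and was -0.01 (SE 0.18) for AA minus PGE2. Cell composition therefore stays open, and a fatty acid effect apart from PGE2 is only a hypothesis, with doses that were not matched.

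Lgr5 was lower with AA at days 1 and 3 and higher at day 6. A single day 6 library did not make this, as the log2 fold change without each of 8 libraries in turn was 0.45 to 0.58 with adjusted p of at most 0.0169. Of the stem cell list with Lgr5, 11 members had a higher response at day 6 than at day 3, 1 lower (Ascl2) and 7 were not called (adjusted p = 0.225 with an estimated correlation), and the median interaction without Lgr5 was 0.57 (SE 0.17, 18 members), short of 2.24 for Lgr5 itself. A batch difference, which no label names, could not be told from the day: the highest mitochondrial rRNA share at day 6 was 0.266%, and every earlier library was above it. The change of direction is therefore left without a cause.

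Libraries were regrouped. In each 3 against 3 comparison, only the real one of 10 splits called as many genes, and 10 are too few for a share under 0.05. The real counts were 6347 for AA at day 1 and 4670 at day 3, and 8297 and 8132 for PGE2. They were 5713 for AA against PGE2 at day 1, 5277 at day 3, and 4925 for vehicle at day 3 against day 1. At day 6 of AA, 1 of 35 splits called as many (4507). The highest other count was 0 in each after adjustment. Every other split mixed both groups, so the real difference widened its spread within groups, and its counts do not show what chance gives. At an unadjusted p under 0.05 the real and highest other counts were 7182 and 202, 5870 and 687, 8725 and 106, 8762 and 157, 6583 and 200, 6471 and 285, 6249 and 484 for the 3 against 3 comparisons in the same order, and 6265 and 2098 for AA at day 6. For differences of responses, 2 of 100 splits called as many for AA at day 3 minus day 1 (real 1983, highest other 2012) and 2 of 100 for PGE2 at day 3 minus day 1 (real 3630, highest other 4086). For AA at day 6 minus day 3 it was 3 of 100 (real 1812, highest other 7618). The highest other splits kept 4 of 6 AA and 0 of 6 vehicle libraries with their own day for AA at day 3 minus day 1, 6 of 6 PGE2 and 2 of 6 vehicle libraries for PGE2, and 7 of 7 AA and 1 of 7 vehicle libraries for AA at day 6 minus day 3. Each thus carried the difference between the days itself.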

How the results depend on the processing

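The fit without rRNA-like loci and mitochondrial genes and the separate naming of libraries whose removal ended a call were chosen after the results were seen, and the other alternatives were planned. Requiring at least 1.5-fold left 2071 genes for AA at day 1, 2254 for AA at day 3, 3810 for PGE2 at day 1, 3950 for PGE2 at day 3, 1132 for AA at day 6, 1143 and 1692 for AA against PGE2 at days 1 and 3, 1570 for vehicle day 3 against day 1, and 873, 1426 and 1051 for the differences of responses (AA day 3 minus day 1, PGE2 day 3 minus day 1, AA day 6 minus day 3); the stricter rule itself makes these smaller. An adjusted p under 0.01 left 2341 for AA at day 6, and 1518, 2350 and 1477 for these differences. With only the groups in the contrast, AA day 6 minus day 3 gave 1812. Leaving out 1 library gave 5388 to 5694 genes for AA at day 1, 5640 to 5736 for AA at day 3, 7637 to 7909 for PGE2 at day 1, 8102 to 8728 for PGE2 at day 3 and 3214 (without AA replicate 3) to 4873 (without vehicle replicate 4) for AA at day 6. It gave 3335 to 3475 and 4854 to 5379 for AA against PGE2 at days 1 and 3, 4973 to 5829 for vehicle, and 2086 to 2716, 3094 to 3551 and 2140 to 3416 for the differences of responses, and the cause was not tested. With replicate number as a block the counts, in the order used for 1.5-fold, were 6333, 6257, 8394, 8837, 4545, 4272, 5825, 6140, 2817, 3745 and 3471, and 8 of 18 and 3 of 8 libraries best matched their own number, so pairing was not used. Only genes with a mean log2 CPM of at least 3 gave an r of 0.746 between AA at days 1 and 3. With an estimated correlation, camera called 4 lists for AA at day 1, 8 for AA at day 3, 3 for PGE2 at day 1, 6 for PGE2 at day 3 and 0 for AA at day 6 (3 at an unadjusted p under 0.05), and fry called 20 for AA at day 1 and 21 for PGE2 at day 1; the cause was not tested. Of 9920 alternatives for 569 named gene results, 9665 left the side of the threshold unchanged, called or not, 237 lost a call and 18 gained one. Among results called in the main fit or the alternative, 0 reversed. Direction was not compared where neither made a call. For 124 list results the numbers were 414, 51 and 31 of 496, with 0 reversed. In simulated counts with few changed genes, 36% to 56% of the smallest and 90% to 98% of 2-fold changes were recovered. Small ones can be missed.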

Other observations

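Further gene groups were chosen after the values were seen, so their tests are descriptive. Of 11 tested genes of stratified epithelium and its cornified envelope, 11 rose at day 1 of AA (median log2 fold change 1.81, list adjusted p = 5.7e-12), 9 at day 3 of AA (1.38), 11 at day 1 of PGE2 (2.82) and 9 at day 3 of PGE2 (1.94), with 0 lower in each. At day 6 of AA 2 of 6 were higher and 1 lower (list adjusted p = 0.912). Of 10 tested gastric epithelium genes, 5 rose at day 1 and 8 at day 3 of AA, and 7 and 9 with PGE2 (medians 1.52, 2.35, 3.08 and 4.66), with 1 lower in each, and at day 3 all 10 were lower with AA than with PGE2.

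Basement membrane genes rose as well, 12 of 14 at day 1 of AA (median 1.02, list adjusted p = 5.7e-12), 10 at day 3 (0.47), 13 at day 1 of PGE2 (1.69) and 13 at day 3 (1.17), with 1 lower in each. At day 6 of AA 8 of 12 rose and 1 fell (list adjusted p = 0.0185, adjusted p = 0.357 with an estimated correlation). Of 6 tested BMP targets, 4 rose at day 1 and 4 at day 3 of AA, and 4 and 4 with PGE2, with 0 lower at day 1 of AA and 1 lower in each of the others, while at day 6 3 of 7 rose and 3 fell.

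A first hypothesis is that AA acts on organoids in part through prostaglandins, which the covariance ratio of 16.0 is consistent with but does not single out. Organoids given AA with a cyclooxygenase inhibitor would separate the possibilities. A second is that AA raises fatty acid oxidation genes by a route apart from PGE2. The list difference (0.51 to 0.58 at day 1, less at day 3) is weak support. Matched doses and sorted enterocytes would test it against the 0.52 shift of enterocyte genes. Another is that Lgr5 recovers with longer exposure, but library content differed along with the day (mitochondrial rRNA share of at most 0.266% at day 6), and libraries of the 3 days made together would be needed.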
